A study of Mus musculus with 5 samples.

How the data were processed

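RNA was measured in 5 libraries from untreated cultures, 3 of the B16 melanoma line and 2 of the Renca renal carcinoma line. Per the labels' protocols, cells grew in DMEM with 10% serum, RNA was purified on columns with DNase treatment, and stranded libraries were made after mRNA capture with 12 cycles of PCR and sequenced as paired 37-bp reads. The submitters' processing notes name Trimmomatic 0.36, kallisto 0.46.0, DESeq2 without a version, and the build mm10, without saying what each was used for. Transcript set, summing to genes and filters are not given in the sources used here.

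The deposited values are TPM per gene symbol, quantile-normalized by the authors according to the name of the deposited file. The table was checked for this: of 15136 ranks above 0 in every library, 96.5% held the same value in all 5 (within 1e-06), and 536 differed by more. Libraries therefore share nearly one distribution, each summing to between 998663 and 998738 TPM. This removes differences in total RNA or composition between the lines and fixes the top values, so an abundant gene at one rank in every replicate has an SD of 0, as Ppia has in B16. It also leaves different floors. The lowest value above 0 was 0.105, 0.103 and 0.0760 TPM in B16 replicates 1, 2 and 3, and 0.00369 and 0.0226 TPM in Renca replicates 2 and 3. Depth is unknown, no interval for counting error is given, and a listed 0 is not a measured absence. None of the 15 control genes used in every cell was at 0 in any library. All 5 value columns were matched to samples by line and replicate number, and 0 columns were left out. The names of the B16 columns hold a further part whose meaning is not given in the sources used here, and the F10 subline is named by the labels.

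From these values log2(TPM + 1) was computed, and the 13733 genes with at least 1 TPM in at least 2 libraries were tested. Limma 3.58.1 in R 4.3.3 was fitted to all 5 libraries with line as the only term and moderated with an intensity trend, two-sided. A gene was called where the Benjamini-Hochberg adjusted p over all tested genes was under 0.05 and the absolute log2 fold change, B16 minus Renca, was at least 1. No count test was used because TPM are not counts. An exact permutation test of 3 libraries against 2 cannot go below p = 0.1, so calls come from the model across genes, with 5.21 degrees of freedom per gene. Simulated libraries of 13733 genes were drawn from each gene's mean over all 5 libraries and its moderated spread, and quantile-normalized. Of 50 genes changed by 1.5 on the log2 scale 100% were recovered, and of 50 changed by 2, 98%. Of 50 each changed by 3 and by 5, 100% were recovered. Of 13533 unchanged genes 10 were called. Few genes were changed, as many up as down, whereas 40.1% of tested genes were called in the data. The simulation therefore does not show how normalization acts on a difference that wide.

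Gene lists (22), tests and thresholds were fixed before the data were examined. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all lists with at least 3 tested members, and again with an estimated correlation and with fry, which asks only whether a list's own genes move one way. Of the list members, 9 had no row. Named genes followed a fixed rule. It took the 4 most strongly higher in each line among called genes with lines that do not overlap and at least 10 TPM in the higher line, without predicted genes. It added the called member most higher in each line of each main list, the most changed member of each supporting, control or other-cell list, Tyr, Dct, Pmel, Pax2, Pax8 and Cdh16 as checks of the labels, and Cdkn2a. This gave 41 genes, of which 2 have near-identical copies. Other list members are given as examples of their list and were chosen after their values were seen.

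Positions come from GENCODE M21 on mm10, where 27915 symbols had one position, 39 several and 272 none. Families of near-identical transcripts among tested genes were found with blastn 2.17.0, using the longest transcript of each gene and at least 97% identity over at least 50% of the shorter transcript and 100 bp. They number 460 with 1319 genes. The reference is of C57BL/6, the strain of B16. Alternatives were other pseudocounts (0.1 and 5), filters, scalings and variance models, other thresholds, a replicate block, each library left out in turn, and the near-identical genes left out or summed.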

Results

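Polyadenylated RNA was sequenced from 2 untreated mouse cancer cell lines grown in culture. B16 (the F10 subline) is a melanoma line of the C57BL/6 strain and was measured in 3 libraries, replicates 1, 2 and 3. Renca is a renal cell carcinoma line of the BALB/c strain and was measured in 2 libraries, replicates 2 and 3. The values are quantile-normalized transcript abundances (TPM) for 28226 gene symbols. TPM keep no record of depth, so the depth of each library is unknown and no counting interval is given. The table listed 15136, 15160 and 15412 genes above 0 in B16 replicates 1, 2 and 3, and 17310 and 16426 in Renca replicates 2 and 3. Fold changes are B16 minus Renca on the log2(TPM + 1) scale, which understates the change of low genes. Levels are means ± SD with n = 3 for B16 and n = 2 for Renca. No fold is given against a line listed at 0 in every library. Gene positions are on mm10.

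The comparison of B16 with Renca asks how the transcriptomes of these 2 lines differ. By calls of single genes, B16 stood apart by its pigment cell genes, and Renca by epithelial, kidney-lineage, interferon-stimulated and MHC class I genes. As lists, 0 of 22 were called with an estimated correlation. The renal tubule list turned direction with either Renca library left out, where the filter removed its genes expressed in Renca alone. Of 13733 genes tested, 5503 were called (limma, Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change), 2789 higher in B16 and 2714 higher in Renca. All 5503 had lines that did not overlap, as did 82.0% of tested genes, where chance gives 20% for 3 libraries against 2. Of the called genes, 591 were listed at 0 in every B16 library and 460 in every Renca library. The split between directions depended on the scaling. With each library centred on the median level of 15 control genes used in every cell, different genes set that level in the 2 lines, the median of all genes moved from 0.07 to -1.79, and the calls became 692 higher in B16 and 10234 higher in Renca. Of the named genes Eng turned under it, and Mtap, Gusb, Cgas, Pycard, Il15 and Canx kept their direction toward B16 but lost the call. With centring on the median deviation of the same genes from their own means, a choice made after seeing the data, the median moved to -0.41 and the calls became 1708 higher in B16 and 4107 higher in Renca. Without Renca replicate 2 the calls higher in Renca fell to 1508, and without Renca replicate 3 to 1560, because genes expressed in Renca alone then no longer reached 1 TPM in 2 libraries.

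Libraries of one line resembled each other far more than those of the other line. Pearson's r across genes was 0.980 to 0.981 within B16, 0.985 within Renca and 0.675 to 0.683 between the lines. Genes are not independent replicates, so these values describe the libraries and test nothing. No pair of libraries held identical values. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Line, tissue of origin and mouse strain coincide in this design, and a difference between B16 and Renca is a difference in all 3 at once.

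Of the 22 gene lists fixed before the data were examined, 12 were called (camera with a preset correlation of 0.01, adjusted p under 0.05), 4 toward B16 and 8 toward Renca. With the correlation estimated from the residuals, 0 of 22 were called, so the list calls rest on the preset setting. A larger correlation does not account for every loss. The estimate was 0.00405 for checkpoint and costimulatory ligands, -0.0208 for MHC class I and -0.0345 for cytokines, all under the preset 0.01. It was above 0.01 for the other lists called. With an estimate, camera also takes its degrees of freedom from the 5 libraries alone, so it has little power here. Calls of single genes depend on neither setting. With centring on the control list's median level 3 lists were called, the pigment cell, interferon-stimulated, and mesenchymal and matrix genes, and the other 10 calls were lost. For every list, the counts of called members adjusted over the list alone equalled those adjusted over all genes. Of 13733 tested genes, 10092 had an adjusted p under 0.05 at any fold change. The 2-fold cut-off, shared by both adjustments, therefore set most calls, and the agreement is no separate support.

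**Figure D1:**
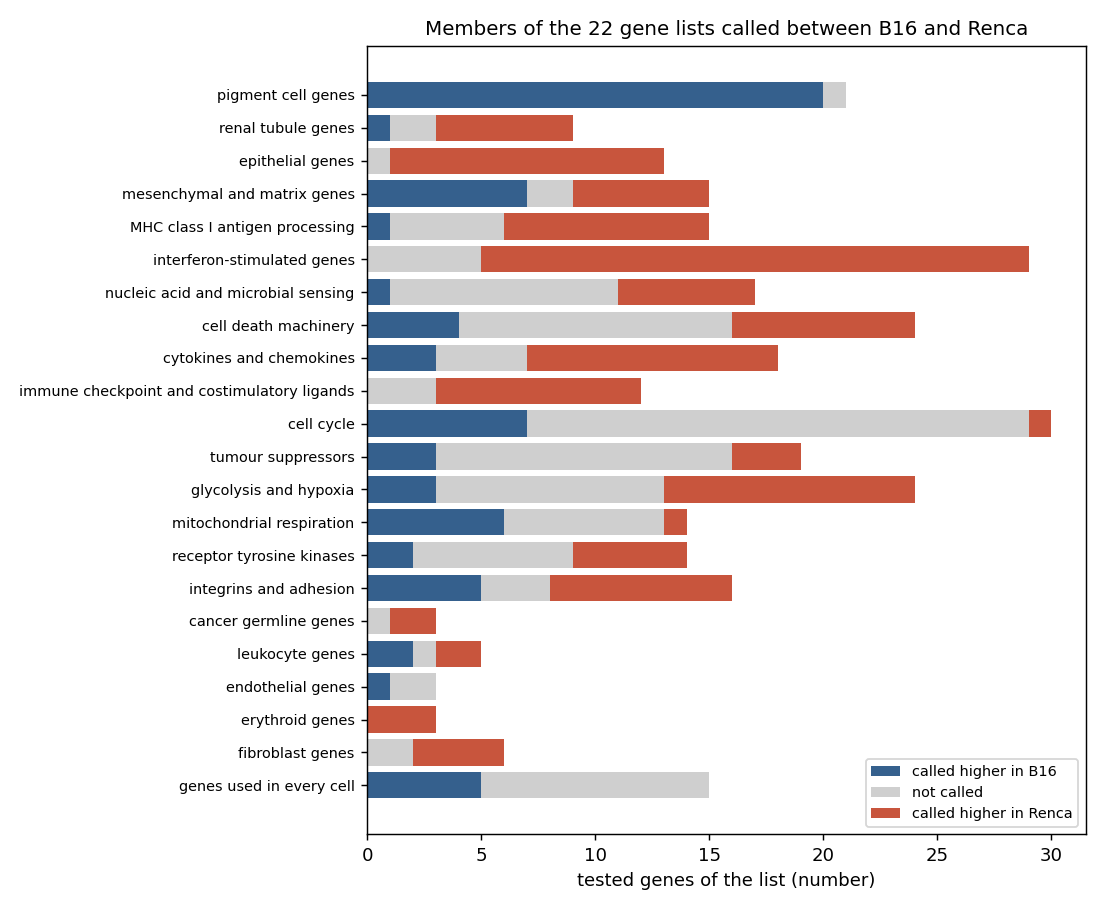
Number of tested genes (x axis) of each of the 22 gene lists (y axis), split into those called higher in B16 (blue), not called (grey) and called higher in Renca (red). Of the pigment cell genes 20 of 21 were called higher in B16, and of the interferon-stimulated genes 24 of 29 were called higher in Renca.

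Pigment cell genes were among the most abundant transcripts of B16 and low or listed at 0 in Renca, apart from Gpnmb at 48.7 ± 3.88 TPM. Of 21 tested, 20 were called higher in B16 and 0 in Renca, with the same 20 adjusted over the list alone. Tyrp1, an enzyme of melanin synthesis (chromosome 4, 80834123 to 80851719), stood at 5714 ± 606 TPM in B16 and was listed at 0 in both Renca libraries. Dct, dopachrome tautomerase (chromosome 14, 118012790 to 118052244), stood at 5412 ± 547 TPM against 0.252 ± 0.0232 (log2 fold change 12.07, SE 0.0952, adjusted p = 3.69e-07). Mlana, a melanosome protein, stood at 4155 ± 303 against 0.701 ± 0.992 TPM (log2 fold change 11.39). Pmel, the fibril protein of melanosomes (chromosome 10, 128704195 to 128720238), stood at 3824 ± 87.2 against 0.699 ± 0.0525 TPM (log2 fold change 11.14, SE 0.0510, adjusted p = 2.18e-07). These 4 were the most strongly higher in B16 of all genes eligible to be named. Tyr, the rate-limiting enzyme of melanin synthesis, was lower in level, at 127 ± 9.46 against 0.0194 ± 0.0164 TPM. The transcription factors Mitf (196 ± 6.20 against 0.703 ± 0.445 TPM) and Sox10 (253 ± 4.96 against 0.248 ± 0.0396 TPM) were also higher in B16. Erbb3 was the 1 tested member not called, at 10.4 ± 0.313 against 12.8 ± 1.79 TPM. The list test gave an adjusted p of 9.47e-10, and an adjusted p of 0.213 with an estimated correlation.

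Kidney-lineage transcription factors were expressed in Renca and listed at 0 in B16. Of 21 renal tubule genes in the table, 12 were too low to test and 9 were tested, 6 were called higher in Renca and 1 higher in B16, with the same counts adjusted over the list alone. Pax8 (chromosome 2, 24420560 to 24475599) stood at 117 ± 11.9 TPM in Renca and Pax2 (chromosome 19, 44756045 to 44837871) at 16.3 ± 2.71 TPM, both listed at 0 in every B16 library. Cdh16, the kidney cadherin, stood at 297 ± 9.53 TPM in Renca against 0.913 ± 0.804 in B16 (log2 fold change -7.37, SE 0.342, adjusted p = 2.53e-05). Cubn, an endocytic receptor of the proximal tubule, went the other way, at 8.57 ± 1.06 TPM in B16 against 0.0793 ± 0.0201 in Renca (log2 fold change 3.14). For the list the adjusted p was 0.0252 toward Renca and an adjusted p of 0.302 with an estimated correlation. The call was lost, and its direction turned, without Renca replicate 2 (adjusted p = 0.949) or 3 (adjusted p = 0.883), and was lost with centring on the control genes' median deviation (adjusted p = 0.118). Without either Renca library the genes expressed in Renca alone left the test.

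Epithelial genes were higher in Renca in 12 of 13 tested and in B16 in 0, with the same 12 adjusted over the list alone. A further 6 of the 19 in the table were too low to test, among them Epcam and Ocln, listed at 0 in every library. The simple-epithelium keratins Krt8 (chromosome 15, 101996698 to 102004482) and Krt18 stood at 412 ± 13.3 and 331 ± 5.39 TPM in Renca and were listed at 0 in all 3 B16 libraries, as was the tight junction protein Cldn3 against 90.0 ± 7.96 TPM. Cdh1, E-cadherin, was low in both lines, at 1.01 ± 0.377 TPM in B16 and 3.17 ± 0.369 in Renca (log2 fold change -1.07). Tested together, they had an adjusted p of 2.38e-05, and an adjusted p of 0.213 with an estimated correlation. The call was lost without Renca replicate 3, and without Renca replicate 2 fewer than 3 members were left to test. In both cases the filter removed genes expressed in Renca alone, such as Krt8.

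Mesenchymal and matrix genes divided between the lines, with 7 of 15 called higher in B16 and 6 in Renca, the same adjusted over the list alone, and no call of the list (adjusted p = 0.683). Cdh2, N-cadherin, stood at 52.3 ± 0.851 TPM in B16 and was listed at 0 in Renca. Zeb2 was higher in B16 (78.4 ± 9.36 against 9.54 ± 0.380 TPM) and its relative Zeb1 in Renca (10.6 ± 1.30 against 0.205 ± 0.203 TPM). Snai2 was higher in B16 (3.15 ± 0.588 against 0.0187 ± 0.0264 TPM), while Snai1 stood at 15.1 ± 3.51 TPM in Renca and was listed at 0 in B16. S100a4 was higher in Renca, at 204 ± 22.6 against 2.96 ± 1.43 TPM (log2 fold change -5.77, SE 0.353, adjusted p = 6.61e-05). Vim, the intermediate filament vimentin, was abundant in both, at 1278 ± 55 TPM in B16 and 1435 ± 170 in Renca, and was not called (adjusted p = 0.144).

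**Figure D2:**
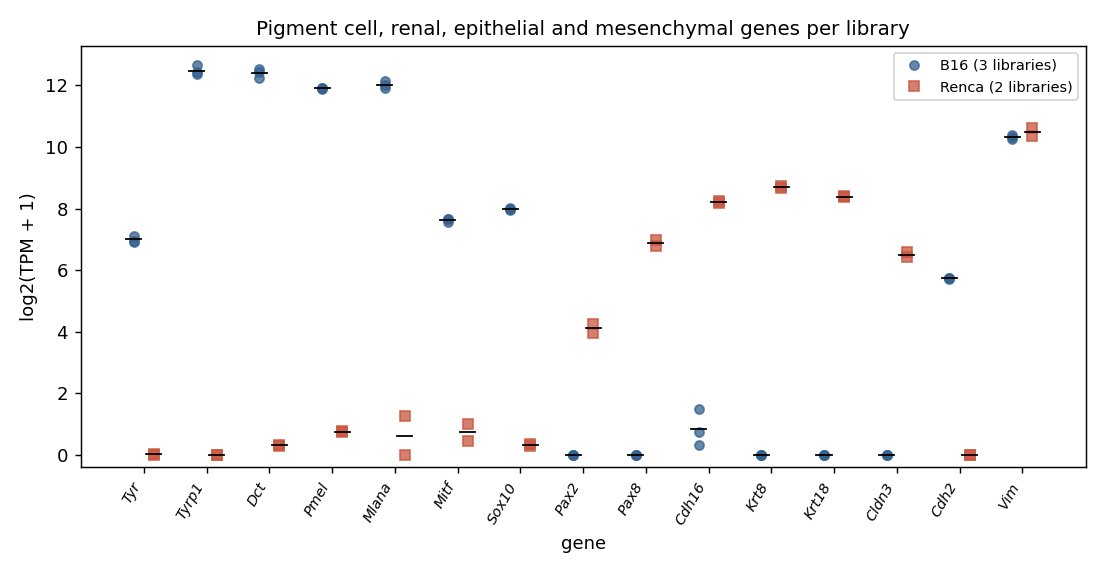
Level of 15 genes (x axis) in each library on the log2(TPM + 1) scale (y axis), with B16 as blue circles and Renca as red squares and the mean of each line as a black bar. The pigment cell genes from Tyr to Sox10 stood high in B16 alone, the genes from Pax2 to Cldn3 in Renca alone, and Vim in both lines.

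MHC class I antigen presentation genes were higher in Renca in 9 of 15 tested and in B16 in 1, the same adjusted over the list alone. The class I heavy chains H2-K1 and H2-D1 stood at 730 ± 57 and 1309 ± 117 TPM in Renca against 10.7 ± 1.67 and 56.3 ± 4.20 in B16 (log2 fold changes -5.98 and -4.51). Their light chain B2m stood at 1272 ± 29.9 against 250 ± 6.84 TPM (log2 fold change -2.34). Psmb8, a catalytic subunit of the immunoproteasome (chromosome 17, 34197721 to 34201454), changed most, at 155 ± 3.08 TPM in Renca against 0.0717 ± 0.124 in B16 (log2 fold change -7.19, SE 0.130, adjusted p = 1.70e-06). Nlrc5, the transactivator of class I genes, stood at 4.77 ± 0.128 against 0.0689 ± 0.0604 TPM. The chaperone Canx, which also serves glycoproteins at large, was higher in B16, at 698 ± 10.5 against 161 ± 0.716 TPM (log2 fold change 2.11). Camera gave an adjusted p of 0.00996, and an adjusted p of 0.270 with an estimated correlation. H2 genes differ in sequence between mouse strains and resemble each other, so the division of reads among single H2 genes is uncertain.

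Interferon-stimulated genes were higher in Renca without any interferon having been added, with 24 of 29 called higher in Renca and 0 in B16, the same adjusted over the list alone. Irf7, a master regulator of type I interferon responses (chromosome 7, 141262706 to 141266481), stood at 264 ± 1.77 TPM in Renca against 0.518 ± 0.225 in B16 (log2 fold change -7.46, SE 0.148, adjusted p = 1.99e-06). Isg15 stood at 520 ± 65.4 against 6.74 ± 1.08 TPM, Ifi44 at 90.8 ± 4.83 against 0.0931 ± 0.0828 TPM, and Bst2 at 830 ± 78.2 against 84.9 ± 4.88 TPM. The signalling components Stat2 (32.4 ± 2.77 against 4.75 ± 0.588 TPM) and Irf9 (35.9 ± 3.03 against 3.66 ± 0.793 TPM) were also called higher in Renca. The 5 members not called were Ifit2, Ifit3, Mx1, Cmpk2 and Gbp2. Of these, Ifit2 stood at 34.3 ± 2.45 TPM in B16 and 19.8 ± 2.21 in Renca, and Mx1 at 4.36 ± 0.262 and 2.64 ± 1.46. As a list these genes had an adjusted p of 6.13e-08, and an adjusted p of 0.302 with an estimated correlation.

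Sensors of nucleic acids and microbes showed a mixed picture. Of 17 tested, 6 were called higher in Renca and 1 in B16, the same adjusted over the list alone, and the list was not called (adjusted p = 0.228). Cgas, the cytosolic DNA sensor, was the gene higher in B16, at 4.21 ± 0.403 against 0.0874 ± 0.0226 TPM (log2 fold change 2.26). That call was lost with a pseudocount of 5 (0.85) and with centring on the control list's median level (0.39). Its adaptor STING, under the symbol Tmem173, was not called, at 22.8 ± 0.820 TPM in B16 and 17.3 ± 2.55 in Renca. Ifi204, an interferon-inducible DNA sensor, was higher in Renca, at 56.3 ± 7.38 against 0.163 ± 0.152 TPM (log2 fold change -5.62). The RNA sensors Ddx58 (41.9 ± 4.50 against 6.80 ± 1.12 TPM) and Ifih1 (13.5 ± 0.860 against 4.95 ± 1.23 TPM) and the adaptor Mavs were also higher in Renca.

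Genes of cell death included 8 of 24 called higher in Renca and 4 in B16, the same adjusted over the list alone, with no call of the list (adjusted p = 0.228). Casp1, the inflammatory caspase, Zbp1, a nucleic acid sensor of necroptosis, and the kinase Ripk3 were listed at 0 in all 3 B16 libraries and stood at 21.6 ± 0.672, 17.4 ± 2.58 and 11.2 ± 1.10 TPM in Renca. The pore-forming Gsdmd stood at 88.0 ± 7.68 TPM in Renca against 3.41 ± 1.57 in B16. Its relative Gsdme was higher in B16, at 10.7 ± 1.30 against 1.83 ± 0.222 TPM. Pycard, the inflammasome adaptor ASC, was also higher in B16, at 42.9 ± 0.397 against 8.91 ± 3.90 TPM (log2 fold change 2.21, SE 0.242, adjusted p = 6.11e-04). Mlkl, the executioner of necroptosis, was not called, at 29.3 ± 1.09 TPM in B16 and 32.7 ± 1.45 in Renca.

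Cytokine and chemokine genes were higher in Renca in 11 of 18 tested and in B16 in 3, the same adjusted over the list alone. Vegfa, the angiogenic growth factor, stood at 629 ± 63.5 TPM in Renca against 27.8 ± 1.35 in B16 (log2 fold change -4.45), and Csf1, the macrophage growth factor, at 78.3 ± 6.75 against 7.63 ± 1.11 TPM. Ccl2, a monocyte chemoattractant, stood at 24.8 ± 6.22 TPM in Renca and was listed at 0 in B16. The genes higher in B16 were Il15 (4.06 ± 2.33 against 0.0292 ± 0.0412 TPM), Il18 and Cxcl10 (26.3 ± 1.09 against 9.98 ± 5.10 TPM). Il15 lost its call with a pseudocount of 5 (log2 fold change 0.82), with centring on the control list's median level (0.33) and under treat (adjusted p = 0.0551). The list test gave an adjusted p of 0.0216, and an adjusted p of 0.270 with an estimated correlation. The call was lost with centring on the control genes' median deviation (adjusted p = 0.102). It was also lost with either Renca library left out. The filter then removed genes expressed in Renca alone, such as Ccl2, so that loss says little about the replicates.

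Immune checkpoint and costimulatory ligands were higher in Renca in 9 of 12 tested and in B16 in 0, the same adjusted over the list alone. The list, named for its ligands, also holds receptors such as Cd40 and enzymes such as Entpd1. Cd40 stood at 29.0 ± 5.60 TPM in Renca against 0.274 ± 0.145 in B16 (log2 fold change -4.55, SE 0.177, adjusted p = 1.38e-05). Cd274, which encodes PD-L1, stood at 15 ± 1.58 against 3.89 ± 0.473 TPM (log2 fold change -1.71), and Lgals9 at 150 ± 14.9 against 25.7 ± 1.94 TPM. Tested together, they had an adjusted p of 3.48e-04, and an adjusted p of 0.213 with an estimated correlation.

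**Figure D3:**
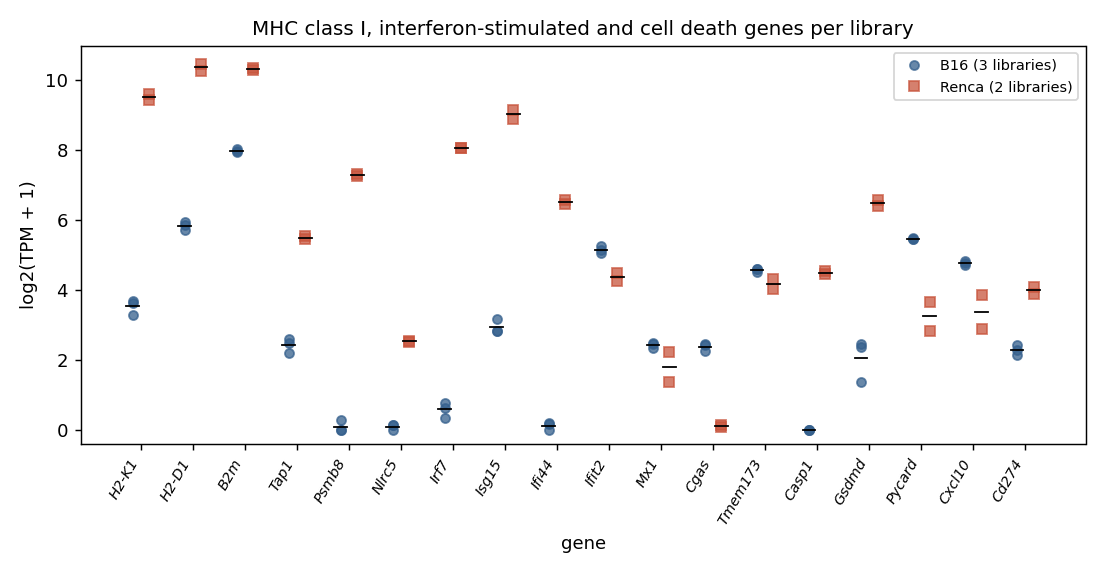
Level of 18 genes of antigen presentation, interferon response, sensing, cell death and immune signalling (x axis) in each library on the log2(TPM + 1) scale (y axis), with B16 as blue circles, Renca as red squares and the mean of each line as a black bar. The genes from H2-K1 to Ifi44 stood higher in Renca, whereas Cgas, Pycard and Cxcl10 stood higher in B16.

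Of 30 cell cycle genes, 7 were called higher in B16, 1 in Renca and 22 not called, the same adjusted over the list alone. The cyclin Ccnd2 (chromosome 6, 127125162 to 127152193) stood at 203 ± 11.2 TPM in B16 against 0.00513 ± 0.00725 in Renca (log2 fold change 7.66), and its relative Ccnd1 was the 1 member higher in Renca, at 222 ± 7.18 against 65.4 ± 1.40 TPM (log2 fold change -1.75). Mcm2, Mcm6, Ccnb1, Plk1, Aurkb and Birc5 were higher in B16. Camera gave an adjusted p of 0.00425, and an adjusted p of 0.302 with an estimated correlation, and its direction turned with the centring on the control list's median level (adjusted p = 0.536).

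Tumour suppressors were mostly not called (13 of 19), with 3 higher in each line, the same adjusted over the list alone, and no call of the list (adjusted p = 0.801). Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 activator Arf (chromosome 4, 89274471 to 89294653), was listed at 0 in all 3 B16 libraries and stood at 288 ± 26.6 TPM in Renca. Its neighbour Cdkn2b (89306299 to 89311039) was likewise listed at 0 in B16 and stood at 22.3 ± 0.442 TPM in Renca. Mtap, the next gene on the other side (89137122 to 89181081), was higher in B16, at 213 ± 11 against 28.4 ± 2.17 TPM (log2 fold change 2.86, SE 0.0765, adjusted p = 4.24e-06). Trp53 was higher in B16 (146 ± 4.72 against 41.0 ± 4.72 TPM). Vhl, the suppressor lost in many renal cell carcinomas, was not called, at 26.4 ± 2.65 TPM in B16 and 39.3 ± 5.53 in Renca.

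**Figure D4:**
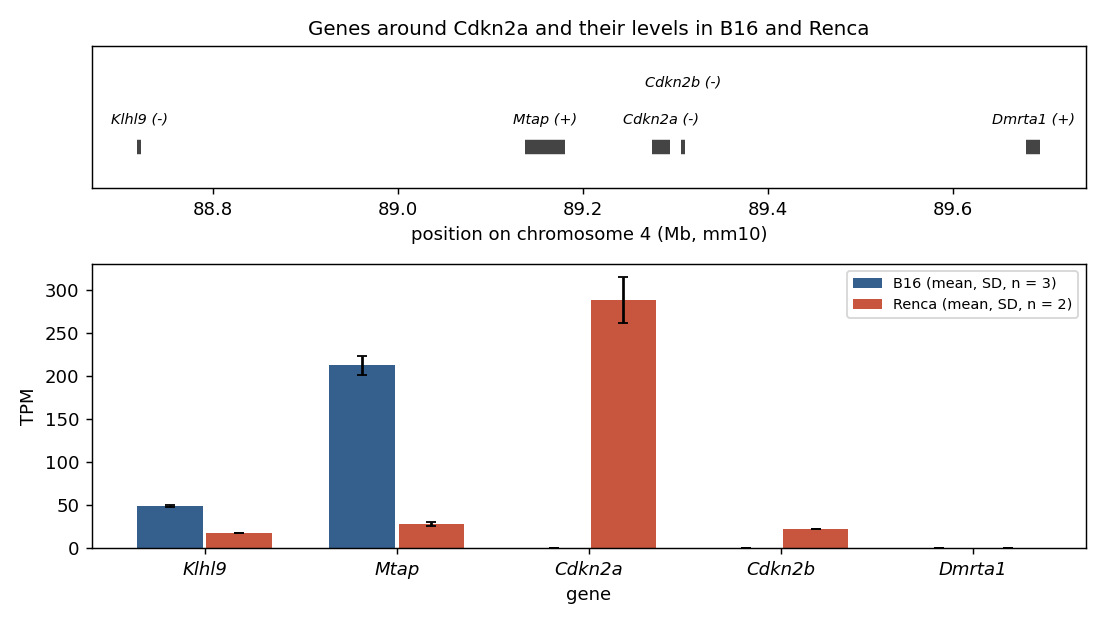
Map of 5 genes around Cdkn2a on chromosome 4 with their strands (upper panel, x axis in Mb on mm10), and their TPM in each line (lower panel, bars start at 0 and show the mean with SD, blue for B16 with n = 3 and red for Renca with n = 2). Cdkn2a and Cdkn2b were listed at 0 in B16, and the neighbouring Mtap stood at 213 TPM there.

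Genes of glycolysis and hypoxia were higher in Renca in 11 of 24 tested and in B16 in 3, the same adjusted over the list alone. The hypoxia-responsive genes Ndrg1 (3024 ± 263 against 66.8 ± 5.33 TPM), Bnip3 (1141 ± 23 against 115 ± 5.30 TPM) and Adm (135 ± 15.5 against 1.24 ± 1.04 TPM) were higher in Renca. The carbonic anhydrases parted, with Car12 higher in Renca (124 ± 7.31 against 0.511 ± 0.0737 TPM, log2 fold change -6.37) and Car9 higher in B16 (21.7 ± 4.89 against 5.16 ± 0.958 TPM). Slc16a3, the lactate exporter MCT4, was higher in B16, at 51.6 ± 0.715 against 0.0914 ± 0.0469 TPM (log2 fold change 5.59). Eno1 was called higher in B16, but Eno1b, its near-identical copy, stood at 835 ± 134 TPM in Renca against 0.985 ± 0.0966 in B16, so the reads of the pair cannot be assigned with certainty. Their family of 3 summed to 3496 TPM in B16 against 2541 in Renca (log2 fold change 0.47). As a list these genes had an adjusted p of 0.0489, and an adjusted p of 0.503 with an estimated correlation. The call was lost without B16 replicate 2 (adjusted p = 0.0579) or 3 (adjusted p = 0.0619), without the variance trend (adjusted p = 0.0588), and with centring on the control genes' median deviation (adjusted p = 0.0956).

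Nuclear genes of mitochondrial respiration were higher in B16 in 6 of 14 and in Renca in 1, the same adjusted over the list alone. Ppargc1a, a coactivator of mitochondrial biogenesis, stood at 31.1 ± 4.43 TPM in B16 against 1.92 ± 0.788 in Renca (log2 fold change 3.48), and Sdhb, Ndufs1, Uqcrc2, Atp5a1 and Idh3a were also higher in B16. For the list the adjusted p was 0.0410, and an adjusted p of 0.302 with an estimated correlation. The call was lost without the variance trend (adjusted p = 0.0541), without Renca replicate 2 (adjusted p = 0.112) and with centring on the control genes' median deviation (adjusted p = 0.0956), and its direction turned with centring on the control list's median level (adjusted p = 0.687). Of the 13 mitochondrially encoded genes, a group counted after seeing the data, 8 were called higher in Renca and 0 in B16, but 5 of these 8 have near-identical copies, so their reads cannot be assigned with certainty. With the copies summed 0 of the 5 stayed at a 2-fold change and mt-Atp6 turned to 0.20 on the log2 scale, while mt-Co1, which was not called, moved to -1.02. The 3 called without such copies were mt-Nd2, mt-Nd5 and mt-Nd6.

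Receptors for growth factors and matrix also differed between the lines, although neither list was called. Of 14 receptor tyrosine kinases 2 were called higher in B16 and 5 in Renca, the same adjusted over the list alone (adjusted p = 0.148). Met, the receptor of hepatocyte growth factor, stood at 237 ± 21.3 TPM in B16 against 4.22 ± 1.08 in Renca, and Fgfr1 at 77.9 ± 4.19 TPM in Renca against 0.731 ± 0.569 in B16 (log2 fold change -5.56). Of 16 integrins and adhesion genes 5 were called higher in B16 and 8 in Renca, the same adjusted over the list alone (adjusted p = 0.335). Mcam, the melanoma cell adhesion molecule, stood at 123 ± 3.35 TPM in B16 against 0.636 ± 0.257 in Renca (log2 fold change 6.25), and the laminin receptor subunit Itga3 at 87.3 ± 9.49 TPM in Renca against 0.817 ± 0.154 in B16.

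Of the 18 cancer germline genes 3 were tested and 2 called, both higher in Renca, the same adjusted over the list alone (adjusted p = 0.0826). Sycp1, a protein of meiotic chromosomes, stood at 3.37 ± 0.164 TPM in Renca and was listed at 0 in B16. Its call was lost with a pseudocount of 5.

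Markers of other cell types were mostly too low to test. Of 14 leukocyte genes 5 were tested and 2 were called in each direction (adjusted p = 0.538), with Cd68, a lysosomal protein of macrophages, at 59.0 ± 4.28 TPM in Renca against 2.35 ± 0.432 in B16. Of 10 endothelial genes 3 were tested and Eng was called higher in B16 (160 ± 6.65 against 50.2 ± 7.26 TPM, log2 fold change 1.66), without a call of the list (adjusted p = 0.187). Eng turned to -0.20 with the centring on the control list's median level. Of 7 erythroid genes 3 were tested and all 3 were called higher in Renca (adjusted p = 0.0836). The highest was Hba-a2 at 5.08 ± 2.38 TPM in Renca, listed at 0 in B16, its call was lost with a pseudocount of 5, and its near-identical copy Hba-a1 makes its reads uncertain. Of 11 fibroblast genes 6 were tested and 4 were called higher in Renca, among them Col6a1 (19.3 ± 0.731 against 0.0427 ± 0.0740 TPM). The fibroblast list was called toward Renca (adjusted p = 0.0444), with an adjusted p of 0.302 with an estimated correlation. That call was lost with the replicate block (adjusted p = 0.0555), without either Renca library, which left fewer than 3 members to test, without B16 replicate 3 (adjusted p = 0.0617) and with centring on the control genes' median deviation (adjusted p = 0.118). The counts of these 4 lists were the same adjusted over the list alone.

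Genes used in every cell were not level between the lines. Of 15 tested, 5 were called higher in B16 and 0 in Renca, the same adjusted over the list alone. Gusb, a lysosomal enzyme, changed most, at 133 ± 7.57 TPM in B16 against 23.1 ± 0.749 in Renca (log2 fold change 2.48, SE 0.0704, adjusted p = 5.10e-06). Actb stood at 2394 ± 147 and 2425 ± 270 TPM and was not called. Of the 5 called, Ppia, Rplp0 and Rps18 have near-identical copies. The list was called toward B16 (adjusted p = 0.0444), with an adjusted p of 0.350 with an estimated correlation, and the call was lost when genes with near-identical copies were left out (adjusted p = 0.300), without the variance trend (0.0558), without B16 replicate 2 (0.0579) or Renca replicate 2 (0.136), and with centring on the median deviation of these genes (0.171).

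Outside the lists, the named genes most strongly higher in Renca were Ly6e, Tagln2, Gdf15 and Eno1b, of which Eno1b ranks by its own row alone, since the sum of its family with Eno1 was higher in B16 (log2 fold change 0.47). Ly6e, a membrane protein induced by interferon (chromosome 15, 74955051 to 74959905), stood at 1189 ± 223 TPM in Renca and was listed at 0 in all 3 B16 libraries. Tagln2, an actin-binding protein (chromosome 1, 172500047 to 172507380), stood at 541 ± 93.7 TPM in Renca and was also listed at 0 in B16. Gdf15, a stress-induced cytokine (chromosome 8, 70629393 to 70632456), stood at 530 ± 34.9 against 0.190 ± 0.329 TPM (log2 fold change -8.83, SE 0.229, adjusted p = 3.92e-06).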

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

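Leaving out or summing near-identical families, centring on the control genes' median deviation and all other settings for the similarity of replicates were chosen after seeing the data. Of 698 values of named genes under other settings, 686 kept their direction and side of the threshold, 11 lost the call and 1 turned (Eng, -0.20 with centring on the control list's median level). Some of these settings could hardly undo a call. Dropping the minimum fold change only loosens the threshold, and rescaling to a common sum acts on sums already nearly equal. The share kept therefore overstates how firm the calls are. A named gene that left the test under a setting is not among the 698. Named genes expressed in Renca alone, such as Pax2, Pax8, Krt8, Cdkn2a and Ly6e, therefore went unchecked when either Renca library was left out. Of 381 list tests under other settings, 326 kept direction and side of the threshold, 40 lost the call, 11 gained it and 4 turned. Lists with fewer than 3 tested members under a setting are not among the 381.

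The 5503 calls (2789 higher in B16 and 2714 in Renca) were 3635 with a pseudocount of 5 (1767 higher in B16), and 10092 with no minimum fold change (5350 and 4742). Calls higher in Renca were 1804 with a mean of at least 5 TPM, where fewer genes were tested. Calls higher in B16 were 1793 when tested against a log2 fold change of 1 by treat. Centring on the control list's median level gave 10926 calls (692 and 10234) and moved the median of all genes to -1.79, because the median gene of that list was Actb or Tuba1b in B16 but Rplp0 in Renca, so different genes set the level. Centring on the control genes' median deviation gave 1708 and 4107. Leaving out each library in turn, where a lone Renca library was assumed to vary like B16, gave 1508 to 2750 calls higher in Renca and 6 to 12 lists.

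The 12 lists called became 3 with the control list's median level, 6 with the control genes' median deviation, 0 with an estimated correlation and 21 with fry. With the control list's median level the tests of cell cycle (adjusted p = 0.536) and mitochondrial respiration (0.687) turned. The renal tubule list ranged from 0.0205 to 0.949 over the left-out libraries, turning without either Renca library. The mean r between lines, 0.679, was 0.546 and 0.749 with pseudocounts of 0.1 and 5, 0.825 without a filter and 0.517 with a mean of at least 5 TPM. Unless said above, the cause was not tested.

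The replicate numbers 2 and 3 are shared by both lines only as numbers. With the replicate block 5625 genes and 11 lists were called. Over 2 such pairs the deviations of same-numbered libraries correlated at -0.0281 across genes. Depth is unknown, so what it limits cannot be given.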

Other observations

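The 2 cell lines also differed in gene groups that were picked after seeing the data and then counted, so the counts describe these groups and no test of them is given. Genes of the integrated stress response, which follow the transcription factor ATF4, were higher in Renca in 14 of 16 tested and in B16 in 0, and Gdf15, named in the report for its large change, is one of them. Atf4 stood at 1614 ± 175 TPM in Renca (n = 2) against 328 ± 31.5 in B16 (n = 3), Trib3 at 381 ± 19.5 against 33.8 ± 7.12, Ddit4 at 1768 ± 27.3 against 32.9 ± 4.02, and the secreted factor Fgf21 at 399.9 ± 10.1 TPM in Renca and listed at 0 in B16. Slc7a11 and Psat1 were the members not called. Chaperones of the endoplasmic reticulum, which mark another branch of the stress response, had 1 of 13 called higher in Renca, 1 in B16 and 11 not called, a contrast that was not itself tested. Hspa5, the main one, stood at 1530 ± 36.0 TPM in Renca and 1313 ± 65.9 in B16.

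Hox genes, which encode position along the body axis, were higher in Renca in 20 of 28 tested and in B16 in 2, Hoxd13 and Hoxd3. Hoxc10 stood at 61.0 ± 2.12 TPM in Renca and Hoxd9 at 36.7 ± 1.05, both listed at 0 in B16, whereas Hoxd13 stood at 10.3 ± 1.34 TPM in B16 and was listed at 0 in Renca. The X-linked reproductive homeobox genes Rhox2d (112 ± 11.8 TPM) and Rhox2g (87.9 ± 1.12 TPM) were expressed in Renca and listed at 0 in B16. Of 23 Rhox rows 4 were tested, and these 4 were called higher in Renca. Rhox2c and Rhox2f were listed at 0 in every library, and the division of reads among the Rhox2 genes was not tested. Of the MHC class I genes of the H2 complex, 15 of 16 tested were higher in Renca and 0 in B16. The values of all 28 such rows summed to 2782 ± 212 TPM in Renca against 99.7 ± 6.35 in B16.

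For the 3 patterns weighed next, the tests of parent against copy and of chance placement were chosen after the results were seen. In 50 families of near-identical transcripts, members were called in opposite directions. Rps2 stood at 3680 TPM in B16 and 42.2 in Renca while its pseudogene Rps2-ps10 stood at 10.2 and 3854, and their family sum differed by only -0.08 on the log2 scale. The family sums had a median absolute log2 fold change of 0.77 against 1.97 for their called members, but unrelated genes matched on level and change gave 0.78 (2.5th percentile 0.67), so this test, which matched away most of what it measures, decides nothing about shared reads. A trade of reads from library to library was not settled either, since parent and copy deviations within a line correlated at a median of 0.0808, above the bound set beforehand (the median of shuffled pairs) but inside their spread (-0.321 to 0.306). In 27 of 37 families with a protein-coding parent and an opposite pseudogene, the parent was higher in B16 (exact binomial two-sided p = 0.00763). B16 is the line of the reference strain. The binomial test takes called parents to lean to neither line otherwise, which was not tested. The other families went the opposite way, and among them was the largest change of a copy. Gm10925, the copy of mt-Atp6, stood at 8679 TPM in B16 against 0.311 in Renca. Strain variants against the reference may direct Renca reads to pseudogenes, a hypothesis that reads could test.

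A run of 10 adjacent expressed protein-coding genes on chromosome 15 (73834561 to 75048830), from Gm6569 and Arc through Jrk, Psca, Them6, Lynx1, Ly6d, Ly6e and Ly6a to Ly6c1, was listed at 0 in every B16 library, while Ly6e stood at 1189 and Them6 at 86.2 TPM in Renca. Chance placement of genes one by one was argued against, since 0 of 1000 shuffles within chromosomes gave a run of 10 (longest 6). The shuffles separate neighbours of one gene family, such as Ly6d, Ly6e, Ly6a and Ly6c1, so they say nothing about joint regulation of such neighbours. Reads shared between near-identical copies were also argued against, since 0 of the 10 genes have such copies among tested genes. Loss of the chromosome segment in B16 predicted that no row inside it reaches 1 TPM there, and of 23 rows 22 stayed under it and 1, the pseudogene Gm15387, stood at 369 TPM, but that bound was set wrongly for it, because it is a near-identical copy of Hmgb1 on chromosome 5 (466 TPM in B16), whose reads it may take. A further pseudogene inside it, Gm7935, stood at 0.926 TPM in B16 and was listed at 0 in Renca, and a search of all genes made after seeing this found it to be a near-identical copy of Sf3b4 (103 TPM in B16), so it decides nothing either. Loss and silencing of the segment cannot be told apart from RNA, and the difference between the lines in tissue and strain stays open and untested.

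Genes of chromosome 6 were shifted toward B16 as a body, and the median log2 fold change of its 586 protein-coding genes lay 1.02 above that of the other autosomes, the 25th percentile 0.99 above and the 75th 0.94 above, and 80% of its genes were higher in B16 against 50.9% on the other autosomes. Other chromosomes were shifted too, less far (at most -0.54, on chromosome 15), and 12 of 20, chromosome 6 included, had a median outside the range of 1000 random sets of their own size. A shift of the whole distribution is what a difference in copy number predicts, but it is not particular to chromosome 6. On chromosome 9 the quartiles were -0.19 and 1.13 (median 0.53), against -0.72 and 0.55 on chromosome 16 (median -0.01). The quartiles therefore do not separate copy number from other causes of a shifted median. On chromosome 6, the medians of 6 windows along the chromosome ran from 0.82 to 1.52. Chance placement of genes one by one was argued against, with 0 of 10000 random gene sets reaching this median (highest 0.28), but random sets reject most chromosomes and so do not single out this one, and also argued against were shared reads, since the shift was 1.01 without the near-identical families. A gain in B16 or a loss in Renca is therefore a hypothesis consistent with these values, and RNA alone does not separate the 2 or exclude regulation by cell type.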
